A study of Arabidopsis thaliana with 4 samples.

How the data were processed

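Small RNA of Arabidopsis roots had been sequenced in 4 libraries, 2 wild type and 2 RDR6(-), grouped by the genotype label of each sample. Replicate numbers follow accession order and only name the libraries. The deposited files give, for each distinct sequence of 18 to 44 nt, its raw read count, not normalized, with 1 file per library and no header. TAIR10 and Bowtie are named, without a role or version, per the submitters' processing notes. The trimming and filters behind these lengths are not given in the sources used here. Sequences without a genome match are among those deposited.

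Reads of 18 to 28 nt were matched to the nuclear, plastid and mitochondrial sequences of TAIR10.1 with no mismatch. A read with k matches counted 1/k at each, so genes with near-identical copies share reads. Reads of 29 to 44 nt stayed in the library totals but in no test. Levels are in RPM, reads per 1000000 of all reads in a library's file. For 21 to 22 nt loci, reads were summed per annotated gene over both strands and rounded, and a read in overlapping genes counted for each, so overlapping and antisense genes cannot be told apart. For 24 nt siRNAs they were summed in windows of 1 kb. Classes of origin (TAS, miRNA, rRNA, tRNA, snRNA, snoRNA, protein-coding, pseudogene, other non-coding, plastid, mitochondrial, intergenic) came from the annotation, with 4 kb downstream of annotated rDNA counted as rRNA. A mature miRNA was counted by reads identical to 1 of 95 listed sequences, typed from memory and located in the genome, and 3 tasiRNA sequences were counted with them. For end modification, reads sharing positions 3 to 17 of a mature sequence were assigned to it, with miRNAs of 1 core pooled. A canonical read was identical to a listed sequence, a shift moved the 5' end by up to 3 nt along the genome, and a tail was non-templated when the read matched the genome only after removal of 1 to 3 nt at its 3' end. Sequence beyond the genome was compared with the coding frame of enhanced green fluorescent protein, also typed from memory.

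The main test for miRNAs, loci, windows and distinct sequences was edgeR's quasi-likelihood test of RDR6(-) against wild type over all 4 libraries, with TMM scaling, filterByExpr and a threshold of 0.05 on the Benjamini-Hochberg adjusted p. Standard errors are the size of the log2 change over the square root of the F statistic. For modified shares of a miRNA, with at least 100 reads in every library, its total reads entered as the offset. The TAS total, size shares, class shares and pooled end classes were compared as mean ± SD with a two-sided exact permutation test, whose smallest p is 0.333. The chi-square test of replicates covered genes with reads in the libraries of a group. Single outlying libraries and other splits of the libraries were not tested.

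The named genes followed a rule. For miRNAs these were up to 10 rises and 10 falls past the threshold with groups apart and a mean of 10 RPM or more, plus the 10 most abundant and the known triggers. For loci they were every TAS locus, the 10 largest rises and 10 largest falls, and up to 10 members per fixed list past the threshold, and for windows and distinct sequences the 5 largest rises and 5 largest falls. For modified shares they were the miRNAs past the threshold, and the 10 most abundant ones are covered by the counts of calls. RDR6 is given in every library. The values of 1 listed gene past the threshold are not reported here. The 7 gene lists held 84 genes (TAS loci, PPR genes, auxin receptors, miR472-targeted NLR genes, TAS siRNA targets, other miRNA targets, silencing machinery), and the miRNA lists were triggers, phosphate, copper, sulfate, nitrogen, machinery, developmental, young and tasiRNAs. Rises and falls were ranked by fitted log2 change. Folds of single loci are ratios of pooled reads scaled by library totals. Against a group at 0 they are set against 3 counts over the group's pooled reads, and with 1 to 3 reads they carry an exact 95% counting interval.

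Alternatives were other scalings (DESeq2 size factors in edgeR, total reads), no count filter, DESeq2's Wald test, single-hit reads, 21 nt reads alone, 1 kb windows in place of genes, 5 kb windows, at least 50 reads for distinct sequences, other denominators and size classes for the TAS total, other weightings of shares, and each library left out in turn. With 1 library left in a group, that library was assumed to vary like the other group. For loci, windows and distinct sequences, counts were simulated once from these libraries, with 66 or 67 changed features per fold. On them the test recovered 14.9% of 2-fold and 86.6% of 4-fold changes among 5700 loci, with 12 false calls of 146. It recovered 43.3% and 95.5% among 31490 windows of 24 nt reads, and 0% and 6% among 124967 distinct sequences, where 27 of 96 calls were false and 98.5% of 16-fold changes were recovered. Software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.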

Results

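Small RNA was sequenced from roots of greenhouse-grown Arabidopsis thaliana, with 2 wild type libraries and 2 libraries of plants labelled RDR6(-). RDR6 is the RNA-dependent RNA polymerase that copies cleaved transcripts into double-stranded RNA, from which Dicer-like enzymes release secondary siRNAs. Both genotypes carry the ecotype label Col 0. The series concerned modification of miRNA ends, and the design text sets the small RNA profile of the mutant against that of the wild type. Wild type replicates 1 and 2 held 20241921 and 21243395 reads, and RDR6(-) replicates 1 and 2 held 18983043 and 21134089 reads. Of the reads of 18 to 28 nt, 84.1%, 82.4%, 85.7% and 85.4% matched the TAIR10.1 genome perfectly in the same order. A floor of 3 counts corresponded to 0.148, 0.141, 0.158 and 0.142 RPM (reads per 1000000 reads of the library). The replicates of a group differed beyond sampling noise, with a chi-square per degree of freedom of 76.9 over 10137 genes in the wild type and of 74.2 over 9268 genes in RDR6(-). The labels do not say whether the libraries came from separate plants, so the p-values measure only the spread between these libraries, which may be technical. Intervals and floors cover counting error only.

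RDR6 (AT3G49500, chromosome 3, 18348974 to 18353673, minus strand, TAIR10.1) gave 3 and 3 reads of 18 to 28 nt in the wild type libraries and 3 and 1 reads in the RDR6(-) libraries. Small RNA reads do not measure the RDR6 mRNA, so these counts do not check the labels, and at this depth no difference was detectable. The trans-acting siRNAs, which are made through RDR6, were the available readout of the genotype.

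The TAS loci, non-coding transcripts that are cleaved by a miRNA and then copied by RDR6, lost nearly their whole siRNA output in the RDR6(-) libraries. Their 21 nt reads summed to 31134 ± 2172 RPM (SD, n = 2) in the wild type and to 46.7 ± 17.2 RPM (SD, n = 2) in RDR6(-), a 666.5-fold difference (log2 -9.38, SD of the log2 ratio 0.551). TAS1A (AT2G27400, chromosome 2, 11721539 to 11722468) gave the most siRNA, with 19025 ± 63.3 RPM of 21 to 22 nt reads in the wild type and 21.8 ± 10.3 RPM in RDR6(-) (log2 -9.82, SE 0.52, edgeR adjusted p = 0.000129). TAS3 (AT3G17185, chromosome 3, 5861491 to 5862437), the source of the siRNAs against auxin response factors, fell from 2601 ± 372 to 10.6 ± 3.16 RPM (log2 -7.97). TAS1B, TAS1C and TAS2 fell, with log2 changes of -9.59, -8.89 and -9.25. TAS1B overlaps AT1G07613 and TAS1C overlaps AT2G39670, and the reads of each pair were not separated. TAS3B (AT5G49615) fell to 1 and 2 reads in RDR6(-) from 50 and 56 in the wild type, a ratio of 34.2 with a 95% counting interval of 11.4 to 168.3. TAS4 (AT3G25795), whose siRNAs target MYB transcripts of the anthocyanin pathway, had 203 and 88 reads in the wild type and 0 in both RDR6(-) libraries, at least 93.8-fold lower against 3 counts over the group's pooled reads (adjusted p = 0.009). TAS3C had 1 read over the 4 libraries and was not tested. All 7 tested TAS loci were lower (7 also when adjusted over the list alone), with a median log2 change of -9.25, or -8.89 with TAS4 at its bound. Of the 3 listed tasiRNA sequences 2 were tested and both fell (2 also when adjusted over the list alone). tasiR-ARF (TTCTTGACCTTGTAAGACCCC, within TAS3, chromosome 3, 5862206 to 5862226) fell from 493.2 ± 23.2 to 0.645 ± 0.0921 RPM (log2 -9.54, adjusted p = 0.00961). TAS1-siR255 (TTCTAAGTCCAACATAGCGTA, 3 genome places, 1 of them in TAS1B at chromosome 1, 18549544 to 18549564) fell from 542.1 ± 233.1 to 0.411 ± 0.313 RPM (log2 -10.42, adjusted p = 0.0182). TAS2-siR1511, the other listed tasiRNA, had no read identical to its listed sequence. The two-sided exact permutation test of the TAS total gave p = 0.333, the smallest that 2 against 2 libraries allow. Both single tasiRNAs lost their call in the test over mature sequences when any 1 library was left out, with adjusted p from 0.0876 to 0.331.

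**Figure D1:**
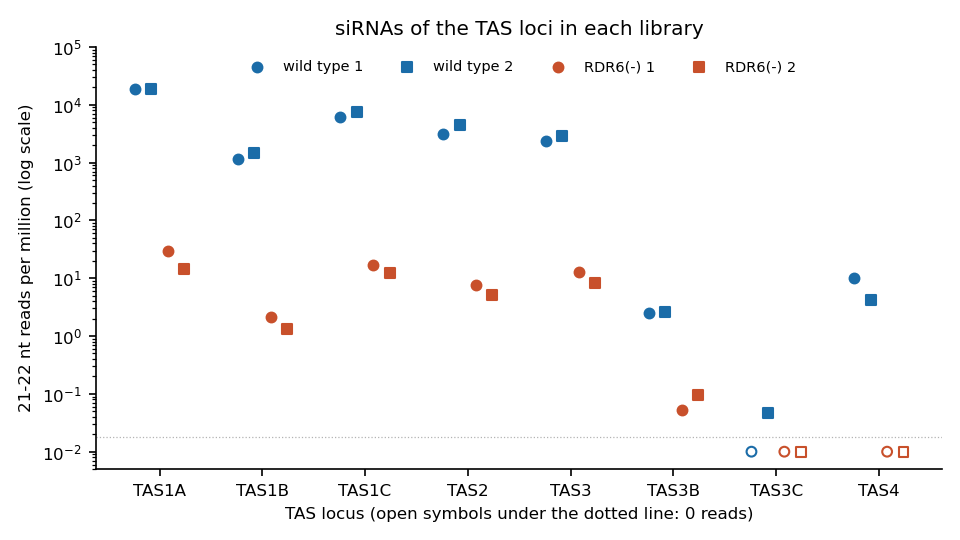
Reads of 21 to 22 nt at each TAS locus, in RPM on a log axis, with 1 symbol per library (2 wild type, 2 RDR6(-)) and open symbols for 0 reads. TAS1A lies at 18980 and 19070 RPM in the wild type libraries and at 29.1 and 14.5 in the RDR6(-) libraries.

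Most tested members of the PPR and auxin receptor lists, coding genes known to give RDR6-dependent secondary siRNAs, had fewer 21 to 22 nt reads in RDR6(-) as well. Of the 23 listed pentatricopeptide repeat (PPR) genes, which encode organellar RNA-binding proteins and are targets of miR161, miR400 and TAS siRNAs, 22 were tested and 21 fell (22 lower when adjusted over the list alone), with a median log2 change of -9.43, or -9.06 with the gene at 0 at its bound. AT1G63130 (chromosome 1, 23412518 to 23415155, overlapping AT1G08597) fell from 616.6 ± 138.8 to 0.226 ± 0.0524 RPM (SD, n = 2 each), a log2 change of -11.39 (SE 0.52). AT1G62910 (chromosome 1, 23298948 to 23301141) fell by 11.58 on the log2 scale. RPF3, a restorer-like PPR gene that processes mitochondrial transcripts, fell by 10.80. AT1G06580 was the tested PPR gene that did not pass over all loci, at 16.4 ± 5.20 and 8.70 ± 1.999 RPM (log2 -0.92, edgeR adjusted p = 0.24). PPR genes share reads with their close copies, and only 3.23% of the reads of AT1G62910 and 58.5% of those of AT1G63130 had a single genome hit, so the value of each member is uncertain. Of the 4 auxin receptor genes targeted by miR393, AFB2 (AT3G26810) fell from 20.5 ± 0.156 to 0.479 ± 0.142 RPM, a 43.4-fold difference in pooled reads (log2 -5.45, adjusted p = 0.00029). AFB3, which overlaps AT1G12810 and AT1G04977, fell by 7.02. TIR1 fell by 1.94 (adjusted p = 0.0223), and AFB1 had 0.844 and 0.584 RPM (log2 -0.57, adjusted p = 0.612). The auxin receptor list had 3 of 4 tested genes lower (3 when adjusted over the list alone) and a median log2 change of -3.69. TIR1 lies on chromosome 3 beyond 11 Mb, and its adjusted p was 0.111 without RDR6(-) replicate 1, 0.054 with 21 nt reads alone and 0.0583 by DESeq2.

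Of the immune receptor genes of the NLR type, the targets of miR472, and of the targets of TAS siRNAs, those called had fewer reads in RDR6(-), while the NLR list as a whole, in which AT1G12290 held most reads, kept 91.59% of its 21 nt reads. Of 16 listed NLR genes 7 were tested and 6 fell (6 when adjusted over the list alone), with a median log2 change of -7.11, or -4.62 with the 3 genes at 0 at their bounds. AT5G43730 (chromosome 5, 17560179 to 17564434, overlapping AT5G43725) went from 248 and 312 reads to 0 and 0, at least 180.5-fold lower. AT1G15890 and AT1G51480, also at 0 reads in RDR6(-), were at least 24.5-fold and at least 25.8-fold lower. AT5G43740, with 1 read in RDR6(-), gave a ratio of 168.3 (95% counting interval 29.8 to 6684). AT5G38850 gave a ratio of 12.3 (3.89 to 62.0). AT1G12290, which overlaps the miR472 gene AT1G12294 and SUMM2, had 358.4 ± 31.7 and 344.3 ± 42.5 RPM (log2 -0.09, adjusted p = 0.936). Of 10 listed targets of TAS siRNAs 3 were tested and all 3 fell (3 when adjusted over the list alone, median log2 -3.47). ARF4, an auxin response factor (AT5G60450, chromosome 5, 24308255 to 24312784), fell from 31.9 ± 14.9 to 0.30 ± 0.0227 RPM, a 107.4-fold difference, ARF3 (AT2G33860) fell by 3.47 on the log2 scale, and ARF2 fell by 2.10. Of 10 other listed miRNA targets 7 were tested and 3 fell (5 lower when adjusted over the list alone, median log2 -2.05). This list includes AGO1, which had been noted beforehand as a gene known to give RDR6-dependent secondary siRNAs. AGO1, the main miRNA effector protein and the target of miR168, fell from 64.6 ± 11.1 to 0.555 ± 0.183 RPM (117.4-fold, log2 -6.91, adjusted p = 0.000358). DCL1, the miRNA processing enzyme, fell by 2.90 and overlaps AT1G03993, AT1G01046 and AT1G01050, and PHB, a leaf polarity factor, fell by 3.17. AGO2, TOE1, REV and PHO2 did not pass, with log2 values of -1.04, -2.05, -1.08 and -0.15 and adjusted p of 0.106, 0.0626, 0.566 and 0.897. The 13 genes of the silencing machinery had too few reads to be tested. AT5G38850 lost its call without RDR6(-) replicate 1 (adjusted p = 0.0894) and without wild type replicate 1 (0.589), and ARF2 lost it with 21 nt reads alone (0.0608) and by DESeq2 (0.0522), while without the loci on chromosome 3 from 11 Mb the 2 genes had 0.0649 and 0.0505.

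Over all annotated genes, 180 of 6306 tested loci lost 21 to 22 nt reads in RDR6(-) and 30 gained them (edgeR quasi-likelihood test, adjusted p under 0.05), and in each of them the 2 groups of libraries did not overlap. The lower loci comprised 123 protein-coding genes, 29 pseudogenes, 23 other non-coding genes and 5 miRNA genes, and 43 of them were on the fixed lists. Changes are ranked here by fitted log2 change, which against a group at 0 reads depends on the prior count, so the bounds and ratios do not follow that order. By this rank the largest falls were at AT1G63615 and AT1G63630, which overlap and share reads (35.6 ± 6.35 RPM in the wild type, 0 reads in RDR6(-), at least 477.7-fold lower). They were followed by AT1G12300 (at least 293.0-fold), RPF2 (ratio 3772, 95% counting interval 1044 to 31150), AT1G63070 (ratio 3442, 952.5 to 28430), AT1G62910, AT1G63130, AT5G43730, AT1G63150 (2155-fold) and AT1G62914 (1908-fold). By the same rank the largest rise was at LCR29, a defensin-like gene (AT2G10535, chromosome 2, 4082851 to 4083168), with 0 reads in the wild type and 4.24 ± 0.0313 RPM in RDR6(-), at least 58.6-fold higher (adjusted p = 0.000765). LCR26, another gene of that family, rose from 0 and 2 reads to 27 and 46 (ratio 37.7, 10.08 to 317.6). AT1G04140, which overlaps AT1G04130, rose from 23 and 11 reads to 550 and 403 (28.99-fold, log2 4.79), and AT2G15340 rose 17.8-fold. AT3G52526 and AT3G52530 overlap and gave ratios of 208.9 and 197.5 (37.1 to 8291 and 35.0 to 7842). AT3G44410 (ratio 38.3, 6.45 to 1552), AT3G43690 (ratio 24.3, 6.36 to 206.5) and MIR849 (17.4-fold) rose too, and these 3 and the AT3G52526 pair lie on chromosome 3 beyond 11 Mb. AT2G04420 had 0 reads in the wild type and 9 and 11 in RDR6(-), at least 6.89-fold higher (adjusted p = 0.0483). Chromosome 3 from 11 Mb held 14 of the 30 higher and 68 of the 180 lower loci, and without its loci 12 of 5597 were higher and 95 lower. Leaving out wild type replicate 1 gave 66 higher and 271 lower loci, and leaving out wild type replicate 2 gave 74 and 267. AT2G04420 lost its call without wild type replicate 1 (0.266), wild type replicate 2 (0.289) or the chromosome 3 loci (0.0657), and AT3G44410 lost it without RDR6(-) replicate 1 (0.122).

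The share of 21 nt reads was lower in both RDR6(-) libraries than in both wild type libraries. Reads of 21 nt, the length of most miRNAs and tasiRNAs, made up 32.1 ± 2.03% of the 18 to 28 nt reads in the wild type and 20.4 ± 3.39% in RDR6(-) (SD, n = 2 each), a difference of -11.7 percentage points. Reads of 24 nt, the heterochromatic siRNA class, made up 27.6 ± 3.61% and 33.6 ± 0.167%, and 23 nt reads 9.85 ± 2.31% and 13.6 ± 0.421%. Longer reads were also higher in both RDR6(-) libraries, with group means of 2.03% and 2.61% at 25 nt, 1.06% and 1.76% at 26 nt, 1.04% and 2.19% at 27 nt and 0.568% and 1.66% at 28 nt. Lower in both were reads of 20 nt (11.5% and 8.10%) and 22 nt (6.80% and 5.69%). By origin, TAS loci gave 3.65 ± 0.214% of reads in the wild type and 0.00595 ± 0.00202% in RDR6(-), and miRNA genes gave 25.8 ± 4.02% and 19.7 ± 3.81%. Pseudogenes gave 3.37 ± 0.241% and 4.62 ± 0.240%, and intergenic sequence 24.9 ± 4.64% and 29.4 ± 1.46%. Among the classes that mark RNA breakdown, rRNA gave 12.9 ± 3.29% and 14.8 ± 3.68%, snRNA 0.0268 ± 0.00469% and 0.0271 ± 0.00383%, and snoRNA 0.0605 ± 0.0253% and 0.0493 ± 0.00323%. tRNA genes gave 5.93% and 5.54% in the wild type libraries and 5.75% and 13.99% in the RDR6(-) libraries. The plastid genome, a sign of green tissue, gave 0.149 ± 0.0848% and 0.108 ± 0.00986%, and the mitochondrial genome 0.288 ± 0.0767% and 0.285 ± 0.0136%. The exact permutation p was 0.333, the smallest possible, for each length named and for TAS, miRNA, pseudogene and intergenic reads, 0.667 for rRNA and tRNA and 1 for the other classes named. Counted over distinct sequences the 21 nt difference was -2.76 and the 24 nt difference 0.904 percentage points.

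**Figure D2:**
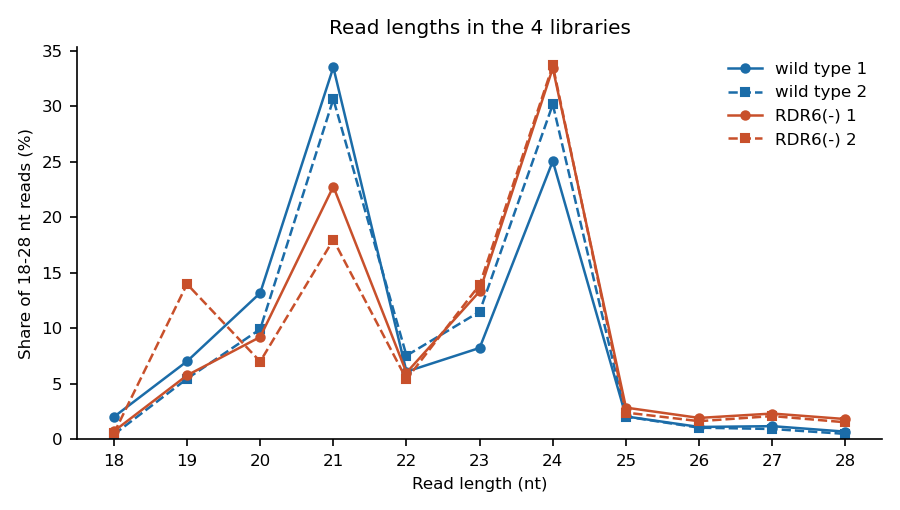
Percent of 18 to 28 nt reads at each length in nt, with 1 line per library (2 wild type, 2 RDR6(-)). The 21 nt share is 33.5% and 30.6% in the wild type libraries and 22.8% and 17.96% in the RDR6(-) libraries.

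Between the genotypes edgeR called 0 of 70 tested mature miRNAs (3 at an unadjusted p under 0.05), while DESeq2 called 5, among them miR173, a trigger of secondary siRNAs. miR173, the 22 nt trigger of TAS1 and TAS2, was at 2960 ± 615 RPM in the wild type and 2016 ± 453 RPM in RDR6(-) (SD, n = 2 each). miR390a, the trigger of TAS3, was at 941.1 ± 3.46 and 1115 ± 410 RPM. miR161.2 was at 812.1 ± 152.5 and 744.9 ± 115.0 RPM, reads identical to the listed miR161.1 at 85.8 ± 10.7 and 65.2 ± 15.5 RPM, and miR472 at 6.22 ± 1.53 and 4.53 ± 0.520 RPM. The listed miR161.1 sequence misses its main read, which starts 1 nt upstream, and all reads sharing its core numbered 216820 and 178879 in the wild type and 177891 and 151871 in RDR6(-). Most reads sharing the core also had a shifted 5' end for miR156h (group means 85.6% and 77.3%), miR160a (61.8% and 79.1%), miR169d (68.8% and 75.4%), miR846 (70.9% and 75.5%) and miR852 (54.8% and 56.7%). Their listed sequences therefore count a minor part of these reads. With all reads sharing the core, edgeR called 0 of 65 miRNA groups. miR393a and miR828 had 10 and 1 reads over all libraries and were not tested. By reads identical to a listed sequence, which leaves out miR161.1, the most abundant miRNAs were miR157a, at 62463 ± 36881 and 37420 ± 28725 RPM, and miR156a, at 56297 ± 13067 and 29673 ± 5227 RPM, regulators of the juvenile phase. They were followed by miR158a (20736 and 21194 RPM), miR166a (17059 and 21531), miR168a (12114 and 10198), miR167a (9917 and 8594), miR165a (3032 and 4925), miR164a (3514 and 2846), miR173 and miR822 (1882 and 1898). Of 95 listed mature miRNAs 70 were tested. The 3 with an unadjusted p under 0.05 by edgeR were miR843 (log2 2.05, adjusted p = 0.171, gene on chromosome 3 beyond 11 Mb), miR156a (-0.94, 0.306) and miR823 (-1.27, 0.471). DESeq2 called miR165a, miR166a, miR843 and miR5026 higher (log2 0.88, 0.52, 2.20 and 1.37) and miR173 lower (-0.39, adjusted p = 0.00963). The fixed lists had no call by edgeR over all sequences and none when adjusted over the list alone: triggers (6 of 8 members tested), phosphate (5 of 6), copper (4 of 5), sulfate (2 of 2), nitrogen (4 of 4), silencing machinery (2 of 2), developmental (19 of 23) and young miRNAs (28 of 45). The median log2 change was -0.16 with TMM and 0.04 with size factors. Counts of 70 features were simulated once from the miRNAs and tasiRNAs together, with few changes put in. On them the test recovered 0 of 7 changes of 2-fold, 1 of 7 of 4-fold (14.3%) and 3 of 6 of 16-fold (50%).

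The miRNAs that respond to phosphate supply varied within each genotype more than between them. miR399f, which targets the phosphate regulator PHO2, was at 22.3 and 287.3 RPM in wild type replicates 1 and 2 and at 16.6 and 231.6 RPM in RDR6(-) replicates 1 and 2. miR827 was at 22.6, 190.1, 33.2 and 360.3 RPM in the same order. miR2111a was at 5.29, 136.2, 4.95 and 79.0 RPM, miR399b at 13.5, 106.2, 16.5 and 80.3 RPM, and miR399a at 1.19, 11.6, 1.21 and 10.7 RPM. miR778, the other listed member, had 4 reads in all. These miRNAs were singled out after their values were seen. None of the 5 passed the genotype test, and their edgeR adjusted p ran from 0.844 to 0.998.

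**Figure D3:**
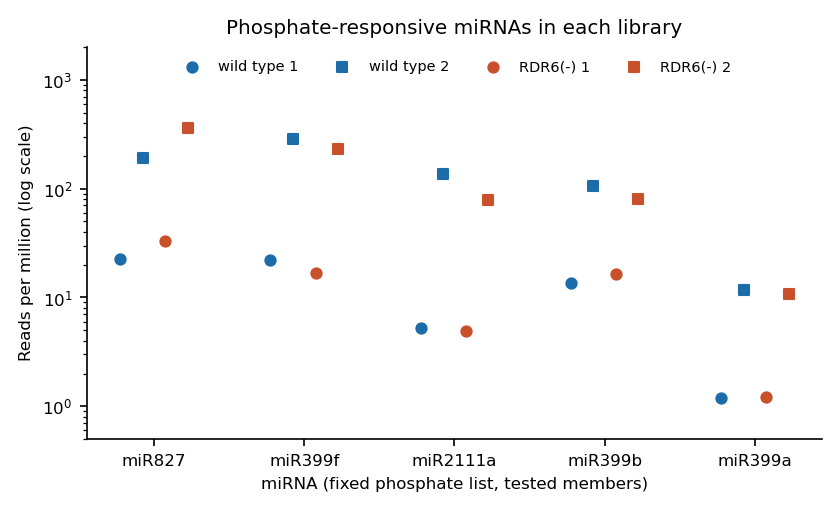
Level of 5 phosphate-responsive miRNAs in each of the 4 libraries, in RPM on a log axis, with 1 symbol per library. miR399f stands at 22.3 and 16.6 in the libraries numbered 1 and at 287.3 and 231.6 in those numbered 2.

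With reads pooled over miRNAs, the 6 main classes of miRNA ends differed between the genotypes by less than the SD of the difference, while reads with other mismatches differed by more. That SD was taken as the root of the summed squares of both group SDs. Over 82 miRNA groups, canonical reads made up 87.1 ± 1.77% of miRNA-derived reads in the wild type and 86.0 ± 1.78% in RDR6(-) (SD, n = 2 each). Reads with a shifted 5' end made up 6.92 ± 0.767% and 7.74 ± 0.635%, and most of them came from miR161.1 (59.5 ± 4.13% and 61.3 ± 0.321%). The most abundant miR161.1 read, TTGAAAGTGACTACATCGGGG, starts 1 nt upstream of the listed start and made up 97.2% of its reads in both groups. Without miR161.1 the shifted share was 2.94 ± 0.628% and 3.15 ± 0.296%. Non-templated 3' tails of 1 to 3 nt, the kind added by the uridylyltransferases HESO1 and URT1 to unmethylated miRNAs, made up 2.07 ± 0.341% and 2.26 ± 0.270%, while averaged over miRNAs in place of pooled reads they made up 4.83 ± 0.0317% and 5.27 ± 0.0411%, a difference larger than its SD (exact permutation p = 0.333). In all, 8 classes were looked at under 5 settings, and other differences beyond their SD are given below. A single U was 48.2 ± 0.674% and 49.0 ± 3.46% of the tails, a single A 8.57 ± 1.03% and 8.85 ± 0.339%, a single C 9.24 ± 1.26% and 7.66 ± 1.39%, and a single G 0.851 ± 0.0113% and 0.872 ± 0.0243%. Templated 3' extensions made up 2.42 ± 0.249% and 2.24 ± 0.227%, shortened 3' ends 0.380 ± 0.0636% and 0.410 ± 0.151%, and non-templated 5' ends 0.302 ± 0.0133% and 0.3599 ± 0.124%. Each of the 6 pooled differences was smaller than that SD, although the 5' shifted one was larger than the SD of either group, and the exact permutation p was 0.667 or 1, where 0.333 is the smallest possible. Between single miRNAs, edgeR called 0 of 49 for the tailed share, 0 for the shortened share and 0 for the 5' shifted share, with 4, 2 and 2 at an unadjusted p under 0.05, and DESeq2 was not run on shares. The nearest was the tailed share of miR408, a copper-responsive miRNA, at 8.82 ± 2.66% and 13.1 ± 2.99% (log2 0.56, adjusted p = 0.0585). On reads simulated once, the test of the tailed share recovered 3 of 5 changes of 2-fold (60%) and 5 of 5 of 4-fold (100%).

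**Figure D4:**
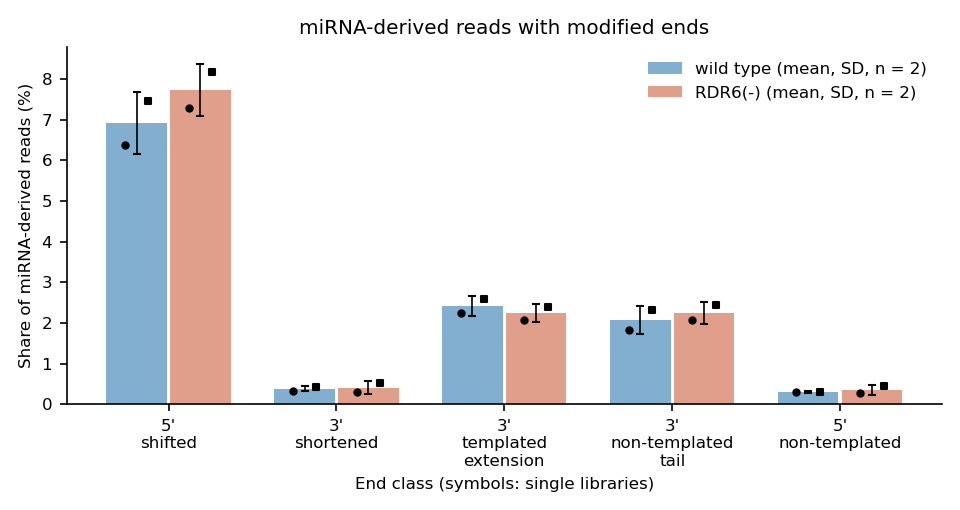
Percent of miRNA-derived reads in 5 classes of modified ends, with bars for the group mean, error bars for the SD (n = 2) and symbols for single libraries. Non-templated 3' tails lie at 1.83% and 2.31% in the wild type libraries and at 2.07% and 2.45% in the RDR6(-) libraries.

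Most 24 nt siRNA windows did not pass the test, and the losses among those that did gathered on chromosome 3 from 11 Mb onward. The 24 nt class is made mainly through RDR2 and is the contrast to the RDR6 products. Of 32076 tested windows of 1 kb, 2233 fell and 806 rose in RDR6(-) (edgeR adjusted p under 0.05). On chromosome 3 from 11 Mb, 30.8% of 5123 tested windows fell and 4.14% rose (median log2 -0.41), and among the other 26953 windows 2.42% fell and 2.20% rose (median log2 0.05). The windows with TAS1A (chromosome 2, 11721001 to 11722000) and TAS1C (chromosome 2, 16537001 to 16538000) fell from 536.4 ± 100.3 to 0.176 ± 0.0486 RPM and from 771.5 ± 38.7 to 0.271 ± 0.0852 RPM, 3064-fold and 2811-fold. By fitted log2 change, the other 3 of the 5 largest falls lay on chromosome 3, at 15796001 to 15797000 (AT3G44005 and AT3G44006, at least 344.6-fold), 15531001 to 15532000 (no annotated gene, at least 283.7-fold) and 18758001 to 18759000 (AT3G50540, ratio 3567, 95% counting interval 639.9 to 140900). The largest rises by the same rank were windows without a read in the wild type, at AT2G04410 and AT2G04420 (chromosome 2, 1535001 to 1536000, at least 243.4-fold), AT5G13350 (chromosome 5, 4282001 to 4283000, at least 226.5-fold), UCNL (chromosome 3, 7286001 to 7287000, at least 189.9-fold), AT3G61028 (chromosome 3, 22583001 to 22584000, at least 148.9-fold) and AT3G43690 (chromosome 3, 15599001 to 15600000, at least 85.8-fold). Scaled to total reads without TMM, 3536 windows rose and 1630 fell, so that the share of rises among the calls went from 26.5% to 68.5% and the median log2 from 0.01 to 0.32. Under that scaling 25.4% of the windows on chromosome 3 from 11 Mb fell and 7.87% rose (median log2 -0.099), and among the other windows 1.22% fell and 11.6% rose (median log2 0.364). Without wild type replicate 1 edgeR called 0 windows in either direction (5589 at an unadjusted p under 0.05) and the 10 named windows had adjusted p from 0.175 to 0.224, with no count filter the UCNL window lost its call (adjusted p = 0.0763), without wild type replicate 2 it called 156 higher and 965 lower, and DESeq2 on all 4 libraries called 438 and 1562.

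**Figure D5:**
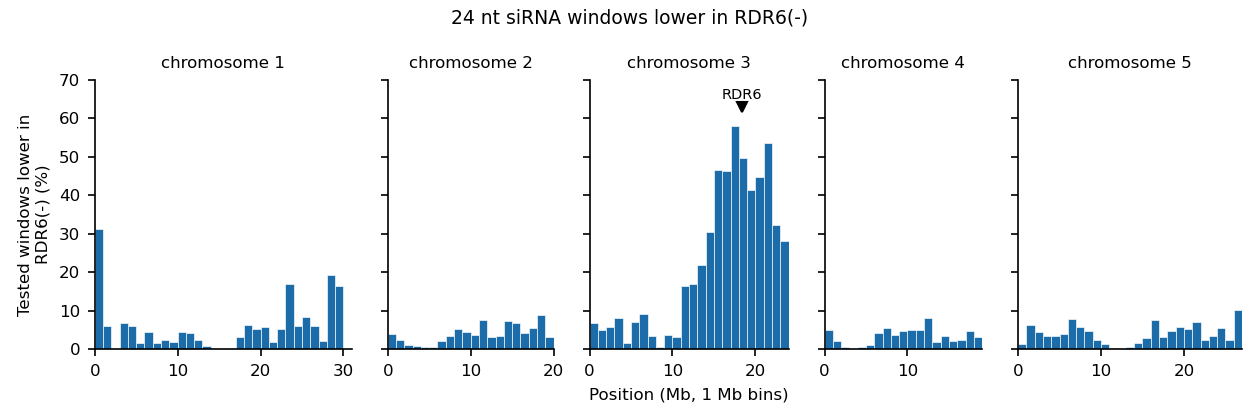
Percent of tested 24 nt windows called lower in RDR6(-), per Mb along the 5 chromosomes (position in Mb), with RDR6 marked on chromosome 3. On chromosome 3 from 11 Mb the share over all windows is 30.8%, against 2.42% in the rest of the genome.

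Tested as distinct sequences, without an annotation, 12219 of 150330 sequences rose and 10878 fell in RDR6(-) (edgeR adjusted p under 0.05). Lengths of 21 and 24 nt, the siRNA classes, held 3320 and 4441 of the sequences that fell, while 23 and 24 nt held 3656 and 6428 of those that rose, and 21 nt 210. No perfect genome match existed for 42.1% of the sequences that rose and 34.7% of those that fell. Of the 5 largest rises by fitted log2 change, 2 had a genome match, both on chromosome 3 beyond 11 Mb and outside annotated genes. AGAACGGAACACAGAAAGAGCAAA (15476264 to 15476287) had 0 reads in the wild type and 64.7 ± 25.8 RPM in RDR6(-), at least 908.6-fold higher, and AGCGGCAACGGGAGAAAAGAAGAA (16911778 to 16911801) had 0 reads and 58.2 ± 7.13 RPM, at least 801.4-fold higher. The other 3 rises, at least 806.6-fold to at least 2621-fold, and all 5 largest falls, at least 2386-fold to at least 2711-fold, were sequences without a genome match. The falls ranked 3 and 4 lay on the coding frame of enhanced green fluorescent protein. That frame held 1133 of the 10878 sequences that fell and 10 of the 12219 that rose. Scaled to total reads without TMM, 19069 rose and 8882 fell, and the share of rises among the calls went from 52.9% to 68.2%. Without RDR6(-) replicate 1 edgeR called 0 sequences in either direction (30611 at an unadjusted p under 0.05) and the 2 named sequences had an adjusted p of 0.0986, without RDR6(-) replicate 2 it called 5739 higher, and DESeq2 on all 4 libraries called 7107 higher and 9047 lower.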

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

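All tests of the green fluorescent protein reads, and 3 of the 5 tests of chromosome 3, were chosen only after the result was seen.

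Reads of 21 to 22 nt without a genome match, which lie outside the comparisons of annotated loci, held many on the coding frame of enhanced green fluorescent protein, at 46232 ± 1843 RPM in the wild type and 15284 ± 739 RPM in RDR6(-) (SD, n = 2 each). In RDR6(-), positions 1 to 400 of the frame stood at 76.4% of the wild type level (134.02%, 97.7%, 57.9% and 45.7% in its bins of 100 nt in order) and positions 401 to 720 kept 0.0253%. Across bins of 100 nt this ratio ranged 5997-fold. That argues against carry-over of wild type reads as the source of all the frame reads, since carry-over alone would give all bins a like ratio. From position 401 on the bins were alike, at 0.0273%, 0.0248%, 0.0223% and 0.0282% of the wild type level, so carry-over at that level stays open there. A transgene in the plants of both groups is a candidate explanation that its tests left open: 79.07% of the 21 nt words of the frame were seen in the poorer wild type library against a bound of 80% in both (82.57% in the other, 0 of the shuffled words), and the longest open reading frame assembled from the reads reached 101 codons, identical over its length, against a bound of 200. The tiling test was written after tiling by bins had been looked at, and a first assembly from 1 seed had reached 30 codons. Whether the last part of the frame is missing from the RDR6(-) plants could not be decided. It still gave 3.97 RPM in the lower of the 2 libraries, which carry-over could also give. Loss of RDR6-dependent siRNA spreading along a transgene stays open as an untested biological explanation.

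The 24 nt losses on chromosome 3 from 11 Mb, the segment that holds RDR6, came with reads that match there with 1 mismatch: 33.19 ± 0.127% of the single-place 1-mismatch reads lay in the segment in RDR6(-) and 10.2 ± 0.0849% in the wild type. The tables argue against library scaling, since with total reads the share of lower windows in the segment was 20.8 times that elsewhere. Whether loss of RDR6 also lowers 24 nt siRNAs wherever they are made could not be decided, since both scalings are relative. TMM centres most windows near no change, and total reads depend on the shares of the other lengths. Under TMM 2.42% of the 26953 windows elsewhere fell and 2.20% rose (median log2 0.05), and with total reads 1.22% fell and 11.6% rose. The difference of 0.464 between the median log2 changes in the segment and elsewhere restates the pattern on a segment chosen for it, so it decides nothing. An effect of RDR6 limited to loci in the segment was not tested and stays open. A stretch of sequence unlike the reference in the RDR6(-) plants may explain the pattern, although both genotypes are labelled Col 0. The tests written beforehand fell short of their bound of 2, with ratios of 1.74 for 1-mismatch sequences and, devised after that, 1.98 for substituted positions (75.2% of 1367 positions seen only in RDR6(-) and 37.9% of 29 seen only in the wild type lay in the segment). In counts, 1028 of the positions seen only in RDR6(-) and 11 of those seen only in the wild type lay in the segment. The ratio of 1.98 thus rests on few wild type positions. Substituted sequence that the wild type libraries lacked was therefore present in the segment in the RDR6(-) libraries. Perfectly matching single-hit 24 nt reads lay there at 7.515 ± 0.290% in RDR6(-) and 12.145 ± 0.403% in the wild type. The test that met the bound, with 3.24 times the percent of 1-mismatch reads in the segment, was chosen after its values and the 11 Mb start had been seen. That such sequence explains the 24 nt losses stays a hypothesis.

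Reads of 29 to 44 nt, which entered no comparison, made up 0.824 ± 0.147% of reads in RDR6(-) and 0.182 ± 0.0807% in the wild type (exact permutation p = 0.333, the smallest possible).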

How the results depend on the processing

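The tests without chromosome 3 from 11 Mb were chosen only after the result was seen, and the other alternatives, the lists and the rule for named genes were fixed before the data were examined. The TAS total kept its direction and size in every setting run (log2 -9.41 to -9.04, and -9.81 to -9.05 with 1 library left out). Of 770 alternative values for 75 named items, 61 of them past the threshold, 25 changed sign, all of them of miRNAs that were called neither by edgeR over all libraries nor in that setting. With a library left out 13 changed sign, 259 were alike and 26 lost the call, and under other settings 12 changed sign, 449 were alike, 8 lost the call and 3 gained it (miR165a, miR166a and miR173 by DESeq2). The log2 change of miR822, -0.01192, became 0.1297 by DESeq2, 0.1296 with size factors, 0.2161 with all reads sharing the core, 0.2408 with no count filter, 0.01184 with total reads, 0.1126 without the chromosome 3 segment and -0.02089 to 0.4913 with a library left out. That of miR161.2, -0.131, became 0.04782 by DESeq2, 0.04777 with size factors, 0.1051 with all reads sharing the core, 0.124 with no count filter and -0.3009 to 0.2875 with a library left out. miR161.1 gave 0.02284 with all reads sharing the core and miR167a 0.06011 with no count filter. With a library left out the ranges were -0.3838 to 0.05278 for miR161.1, -0.2283 to 0.1307 for miR167a, -1.564 to 0.05256 for miR157a, -0.2658 to 0.1221 for miR164a, -0.3251 to 0.1208 for miR168a and -0.6779 to 0.02614 for miR472. For miRNAs DESeq2 called 4 higher and 1 lower where edgeR called 0, and each of the leave-one-out fits called 0. For loci (30 higher, 180 lower), 1 kb windows gave 92 and 428 and no count filter 87 and 319, both with more features tested, the fit without the chromosome 3 segment gave 12 and 95 with fewer, and leaving out 1 library gave 21 to 74 and 151 to 271. For 24 nt windows (806 and 2233), 5 kb windows gave 459 and 992, no count filter 67 and 420, DESeq2 438 higher, total reads 3536 higher, the fit without the segment 286 and 387, and leaving out 1 library 0 to 972 and 0 to 2051. For distinct sequences (12219 and 10878), DESeq2 gave 7107 higher, total reads 19069 higher, a minimum of 50 reads 5847 and 5913, and leaving out 1 library 0 to 12294 and 0 to 15993. Apart from the number of features or libraries in a fit, the cause was not tested. The 21 nt share difference of -11.7 points was -2.76 over distinct sequences. The 24 nt difference of 5.95 points was 0.904 over distinct sequences and 10.02 without rRNA, tRNA, snRNA and snoRNA reads. For end classes, the mean over miRNAs moved the 3' shortened difference from 0.0308 to -0.255 points and the 5' non-templated one from 0.0579 to -0.0863, all within the SDs of the differences, and that of 3' tails to 0.442, beyond its SD of 0.052, and no modified share of a single miRNA was called in any setting. Without the most abundant miRNA, the differences of templated 3' extensions (-0.465 points, SD 0.135), 5' shifted reads (0.488, SD 0.417) and mismatched reads (0.199, SD 0.0815) exceeded their SDs. With sequences of at least 2 reads that of mismatched reads did too (0.175, SD 0.145). For distinct sequences no fit without a count minimum was run, since it was too large. No paired analysis was possible because the replicate numbers are accession order only. Depth limits the loci with few reads, such as the NLR genes, of which 9 of 16 were not tested.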

Other observations

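The tests of the phosphate pattern were chosen only after the result was seen, and so were the genes named here outside the fixed rule.

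At the TAS loci and the listed PPR genes 24 nt reads were also lower in both RDR6(-) libraries than in both wild type libraries, and so they were at the auxin receptors (38.73% of the wild type level) and the other miRNA targets (80.5%), while the NLR list stood at 107.7% and the TAS target list at 94.93% and their groups overlapped. These sums were not tested. The auxin receptors had only 32 and 30 reads against 15 and 8, and the other miRNA targets 34 and 36 against 28 and 26. In the NLR list AT1G12290 alone gave 338 reads in the wild type and 365 in RDR6(-). At the 8 TAS loci 24 nt reads went from 2307 ± 314 RPM in the wild type to 1.58 ± 0.0844 RPM in RDR6(-) (SD, n = 2 each), or 0.0684% of the wild type level, beside 0.15% for 21 nt reads. At the 23 PPR genes they went from 65.5 ± 1.70 to 0.820 ± 0.184 RPM. Further genes outside the lists lost 21 to 22 nt reads. AT3G23690, a basic helix-loop-helix gene and a target of miR393, went from 58.9 ± 14.3 to 0.803 ± 0.131 RPM (74.1-fold, log2 -6.20, edgeR adjusted p = 0.000283). The laccase genes LAC3 and LAC13, targets of the copper-responsive miR408, fell as well, LAC3 from 15.5 ± 6.80 to 0.179 ± 0.119 RPM (89.7-fold) and LAC13 from 35 and 81 reads to 2 and 1 (ratio 37.4, 95% counting interval 12.5 to 184.0). AT1G64583, next to the listed PPR gene AT1G64580, went from 579 and 538 reads to 1 and 0 (ratio 1080, 193.5 to 42700).

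Reads of 19 nt from tRNA genes numbered 2645614 in RDR6(-) replicate 2 and 864282, 884618 and 766767 in wild type replicates 1 and 2 and RDR6(-) replicate 1. Among reads with non-templated bases at the 5' end of a miRNA, a single A made up 27.9 ± 1.06% in the wild type and 7.55 ± 1.62% in RDR6(-), a single G 16.5 ± 0.592% and 5.40 ± 0.00318%, and mixed additions of 2 to 3 nt 32.9 ± 0.541% and 62.95 ± 4.33%. Per 1000000 miRNA-derived reads, those with a single A numbered 842.6 ± 5.13 and 261.5 ± 35.4, and those with a single G 498.4 ± 39.8 and 194.5 ± 67.3. These were picked from 14 kinds of added bases, with an exact permutation p of 0.333, the smallest possible. Among 24 nt windows, the first Mb of chromosome 1 had 31.3% of its 64 tested windows lower in RDR6(-).

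Phosphate-responsive miRNAs stood apart within each genotype, with library 2 over library 1 at a median log2 of 3.29 in the wild type and 3.44 in RDR6(-). The copper list moved the same way, with medians of 1.96 and 2.13 and all 4 members with enough reads higher in library 2 of each genotype (lowest 0.324 and 1.82). A mix-up of libraries between the genotypes is argued against by the TAS siRNAs, where the lowest wild type library had 503 times the reads of the highest RDR6(-) library. A like shift of all miRNAs is argued against by the developmental miRNAs, since the phosphate list exceeded their median log2 by at least 3.085 in both groups. Single developmental miRNAs ranged from -3.20 to 1.92 in the wild type and from -1.80 to 1.22 in RDR6(-). A difference in miRNA composition between the libraries therefore stays open. A difference in phosphate supply, or a wider difference in nutrient supply or growth between plants, stays open. The lead of the phosphate list over the copper list, at least 1.307 on the log2 scale in both groups, restates the pattern on miRNAs singled out for it and tests neither. The labels give no nutrient treatment, and no biological explanation from the design was tested.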
